A study of Mus musculus with 3 samples.

How the data were processed

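Total RNA from microdissected mouse otic placodal ectoderm at the 4 to 8 somite stage was compared between 2 genotypes, embryos heterozygous for null alleles of both Fgf3 and Fgf10 (double heterozygotes) and embryos homozygous for both (double nulls). Per the labels, each genotype gave 3 biological pools of 10 placodes, the RNA was amplified and labelled with Agilent's low-input linear amplification kit for 2 colours, and each of 3 arrays carried 1 pool of each genotype. The double heterozygote was labelled with Cy3 and the double null with Cy5 on all 3 arrays, so that a dye effect of a probe could not be separated from the genotype. The arrays were positions on the same slide and, per the file headers, were read in the same scan session, so no batch of slides or scans had to be tested.

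Per the submitters' processing notes and the file headers, the authors extracted spot values with Agilent Feature Extraction 9.5.1.1. The deposited scanner files hold mean spot intensity and median local background intensity per channel, not yet normalized. They also hold the scanner software's processed intensity, background-subtracted and dye-normalized per the file headers, and its log10 ratio of Cy5 over Cy3. The authors' deposited series table holds log2 ratios, and its values equalled the scanner's log10 ratio converted to log2 within 2.01e-06, on 26245, 27690 and 28017 spots of the 3 arrays. Its column medians were -0.012, -0.0082 and -0.0031, so direction and scale were settled by this match. Spots without a value there were not used in that table. Probe positions are those of the files, on the mouse build mm7 (NCBI35) named in their headers.

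Each array held 45018 spots, of which 43379 were not controls, and these belonged to 41174 probes. Background was corrected with normexp at an offset of 50, and log2 ratios were normalized within arrays by loess with a span of 0.3 and control spots at weight 0. Between 143 and 175 spots per array carried a non-uniformity or population outlier mark and were left out. At most 1 spot per array was saturated. Spots of a probe were averaged, and a probe was kept if it was well above background in Cy3 on all 3 arrays or in Cy5 on all 3, which left 25514 probes. Probes were named through RefSeq gene records of the GRCm38.p6 assembly, used for names only: 22951 by accession, 6659 by symbol and 3109 by an older synonym, while 8455 kept the name in the files. A gene with several probes was represented by the probe of highest mean intensity, which gave 16842 genes.

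The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors are the moderated ones from this fit, and n is 3 arrays for every value unless stated. The estimated prior degrees of freedom were 4.21. The 24 gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Depth in the sense of counts does not apply to arrays, and the number of arrays limits the precision.

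The fit was tested on simulated ratios for 16842 genes and 3 arrays with the prior spread fitted to the real data. Of 100 genes simulated at a log2 change of 0.5, 85 were called, and of 100 simulated at 1, 100 were called. Of 16600 genes simulated without a change, 18 were called and 5.26% had an unadjusted p under 0.05. These simulations held no dye effect.

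The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule took Fgf3 and Fgf10, the 10 largest rises and 10 largest falls among genes past the threshold with one sign on all 3 arrays (clone, predicted and accession-like names left out), up to 4 members of each list past the threshold over all genes or over the list alone, and from a list with none the 2 tested members of highest mean intensity. Members of the FGF feedback, otic and preplacodal lists that did not pass could be named with their values. A few genes that met the rule are not named in the text, and the counts and list tests include them. Alternatives were 2 other background treatments, the scanner's processed signals, other normalizations within and between arrays, other probe filters and probe rules, separate-channel fitting, array weights, an intensity trend in the prior, each array left out in turn, the series table, other thresholds, and outlier spots kept. Loess on probes above background with spans of 0.3, 0.1 and 0.05, a restriction to genes of mean log2 intensity up to 15, and the recentring of the median-centred ratios on the tested genes were chosen after seeing the data. No part of a gene's deleted sequence was given in the sources used here, so where the Fgf3 and Fgf10 probes lie relative to the null alleles was not analysed here.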

Results

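Otic placodes are the patches of head ectoderm that form the inner ear, and Fgf3 and Fgf10 encode fibroblast growth factors that signal to this tissue. The arrays compared placodes that lacked both factors with placodes carrying 1 working copy of each. Each of the 3 arrays measured 1 pool of 10 double null placodes against 1 pool of 10 double heterozygote placodes. Between 26452 and 28258 spots per array were well above background in the double heterozygote channel, and between 27284 and 29177 in the double null channel. Median spot intensities were 110, 118.6 and 129 in the double heterozygote channel and 242.5, 227.5 and 242.9 in the double null channel. Across genes, log2 ratios of pairs of arrays correlated with r between 0.39 and 0.47, where genes are not independent replicates. All log2 ratios below are double null over double heterozygote.

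The targeted genes were examined first. The single Fgf3 probe, at chromosome 7 positions 141266006 to 141267865 of mm7, had a log2 ratio of -0.48 ± 0.13 (SE, n = 3), a fold of 0.716, with limma adjusted p = 0.11. Its array values were -0.69, -0.06 and -0.69, and without replicate 2 the ratio was -0.69 with adjusted p = 0.0177. The Fgf10 probe, at chromosome 13 positions 115999939 to 115999998 of mm7, had a log2 ratio of 0.14 ± 0.09 (SE, n = 3) with adjusted p = 0.368, and its array values were 0.31, -0.11 and 0.23. Both probes were well above background in both channels on all 3 arrays. Whether either probe lies in the deleted part of its allele was not given in the sources used here, so these values do not check the genotype labels.

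Genes of the early otic program and of FGF signalling were among those lower in the double null. Hmx3 and Hmx2, neighbouring homeobox genes needed for the vestibular part of the inner ear, fell by 1.01 ± 0.18 and 0.59 ± 0.08 on the log2 scale (SE, n = 3), with limma adjusted p = 0.049 and 0.0207. The transcription factor gene Sox9 fell by 0.69 ± 0.12 (adjusted p = 0.0438). Dusp6, an ERK phosphatase gene induced by FGF signalling, fell by 0.50 ± 0.06 (adjusted p = 0.0148), and Spred3, an inhibitor of the same pathway, by 0.44 ± 0.07 (adjusted p = 0.0376). The cyclin gene Ccnd1, also in the list of genes flanking Fgf3 and Fgf10, fell by 0.33 ± 0.05 (adjusted p = 0.0347). None of these otic and FGF genes passed when only genes of mean log2 intensity up to 15 were tested. With median centring Dusp6 and Ccnd1 fell less and did not pass. The keratin gene Krt23 had the largest fall of all named genes, with a log2 ratio of -1.84 ± 0.25, or 0.279 of the double heterozygote level (adjusted p = 0.021). In all, 411 of 16842 genes passed the threshold, 93 lower and 318 higher in the double null, each with one sign on all arrays that measured it.

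Other named falls were Dusp16, a phosphatase gene of the JNK and p38 kinases, at -1.02 (adjusted p = 0.00795) and Mdfi, an inhibitor of myogenic factors, at -0.71 (adjusted p = 0.0111). Gpr83, a G protein-coupled receptor gene, fell by 0.67, Rprd1b by 0.66, the opioid precursor gene Pdyn by 0.60 and Ogfr by 0.57, with adjusted p between 0.00842 and 0.0229. The other probes of some of these genes gave smaller ratios: -0.04 and -0.08 for Dusp16, -0.02 for Rprd1b, -0.24 for Gpr83, -0.17 for Ogfr, and -0.0040 and -0.40 for Sox9, whose mean over all probes was -0.37 (adjusted p = 0.108). The second Mdfi probe gave -0.55.

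The largest named rises were Gt(ROSA)26Sor, a noncoding transcript of the Rosa26 locus, at 1.74 ± 0.10 on the log2 scale (SE, n = 3, 3.33-fold), and the muscle determination gene Myod1 at 1.24 ± 0.06 (2.35-fold), both with limma adjusted p = 0.00286. Adm, which encodes the vasodilator adrenomedullin, rose by 1.17 ± 0.18 (adjusted p = 0.0339), Tnni1, a slow muscle troponin gene, by 1.15 ± 0.10 (adjusted p = 0.0043), the metallothionein gene Mt1 by 1.12 ± 0.16 (adjusted p = 0.0236) and the chromatin remodelling gene Dpf1 by 1.09 ± 0.07 (adjusted p = 0.00286). Tnni1 was well above background in the double heterozygote channel on 2 of 3 arrays, its ratio was 2.29 with the processed signals and 1.97 in the deposited ratios, and its second probe gave 0.71, while the second Mt1 probe gave 0.40. The other 4 of the 10 largest rises were the ribosomal protein genes Rps23 (1.02), Rps12 (1.00) and Rps14 (0.96) and the glycolytic gene Ldha (0.96). These 4 were among the brightest genes on the arrays, and a second probe gave -0.14 for Rps12 and 0.42 for Ldha. With the scanner's processed signals these 4 lost their calls, as did every other called gene. Their log2 ratios were then 0.43 for Rps23, 0.58 for Rps12, 0.47 for Rps14 and 0.42 for Ldha.

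**Figure D1:**
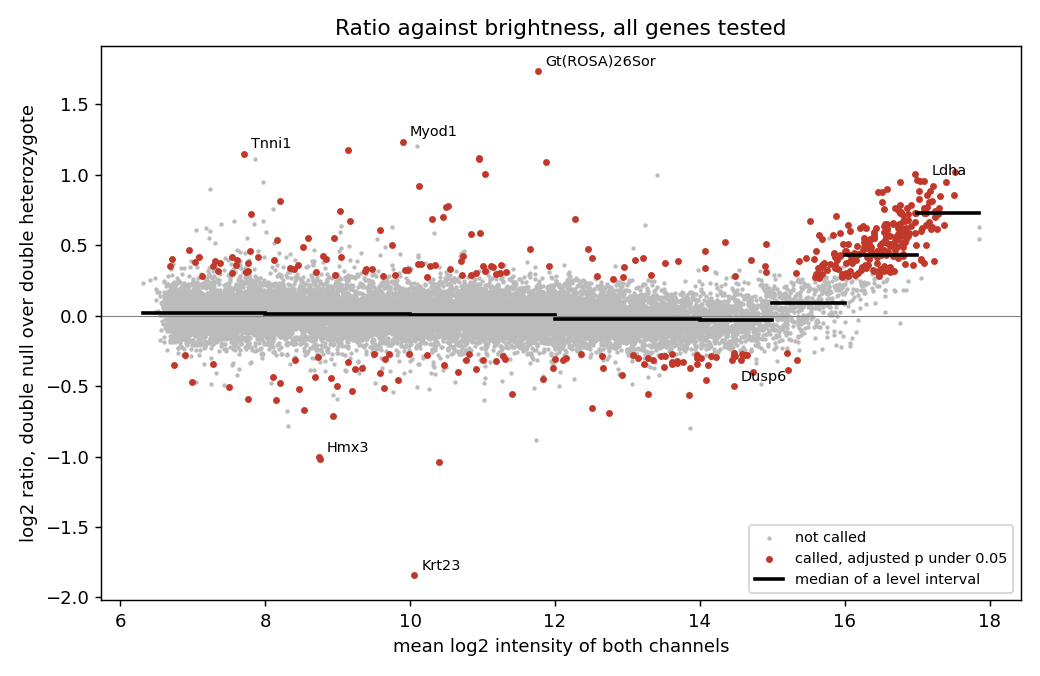
Log2 ratio of double null over double heterozygote (vertical axis) against mean log2 intensity of both channels (horizontal axis) for the 16842 genes tested, with the 411 called genes in red and the median of each intensity interval as a black line. The medians, here from the main loess, lie between -0.03 and 0.02 up to an intensity of 15 and reach 0.43 between 16 and 17 and 0.73 above 17. Most genes called higher are found at intensities over 15.

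The ratio depended on brightness. Of the 318 genes called higher, 217 had a mean log2 intensity over 15, against 3 of the 93 called lower, and the median ratio of the 41 genes above 17 was 0.73. The size of this rise depended on the normalization. Above 17 the median was 0.22 with the processed signals and 0.17 with loess of span 0.1. Between 16 and 17 it was 0.07 and 0.05, against 0.43 in the main fit. With the scanner's processed signals limma called 0 genes (3218 at unadjusted p under 0.05). From the authors' deposited ratios it also called 0 (3268 at unadjusted p under 0.05), and without replicate 3 it called 68. In the main fit 3733 genes had an unadjusted limma p under 0.05. Restricted to genes of intensity up to 15, a choice made after seeing the data, 21 genes passed, 3 lower and 18 higher. Of the genes above, Gt(ROSA)26Sor, Myod1, Dpf1, Tnni1, Dusp16 and Ogfr remained past the threshold there, while the 7 FGF feedback and otic genes, with unchanged log2 ratios, had adjusted p between 0.069 and 0.104. The calls of these 7 genes over all genes thus depended on the bright genes being tested with them.

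Among the gene lists, the otic placode and early otocyst list stood lowest. Of its 21 tested members 18 had a negative ratio, with a median of -0.15. Over all genes 4 fell and 0 rose, and adjusted over the list alone 7 fell and 0 rose, which adds Eya1 (-0.22, second probe -0.0020), Gata3 (-0.41) and Pax8 (-0.23). With camera the list was lower than other genes at adjusted p = 1.3e-05, and adjusted p = 0.432 with an estimated correlation. With fry its adjusted p was 0.211 in one direction and 0.122 for change in either direction.

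The FGF feedback and ERK target list moved in both directions. Of 19 tested members 3 fell over all genes, and adjusted over the list alone 7 fell and 2 rose. The additional falls were Phlda1 (-0.43), the ETS factor genes Etv4 (-0.39) and Etv5 (-0.32) and the feedback inhibitor gene Spry1 (-0.20), and the rises were the stress-inducible gene Ier3 (0.64) and Dusp14 (0.26). Other feedback genes stayed close to 0 without passing, among them Spry2 (-0.05), Spry4 (-0.09) and Dusp4 (-0.09). The median of the list was -0.09, camera gave adjusted p = 0.044, and the adjusted p was 0.432 with an estimated correlation. The FGF ligand and receptor list, with Fgf15 at -0.20 and Frs2 at 0.11, had 0 of 11 members past the threshold and camera adjusted p = 0.853. Its median was 0.0081 and its mean -0.02. The head mesoderm list also differed in sign, with a median of 0.03 and a mean of 0.0042 but a downward camera result, as did the neurogenesis list, with a median of 0.01 and a mean of 0.00035.

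**Figure D2:**
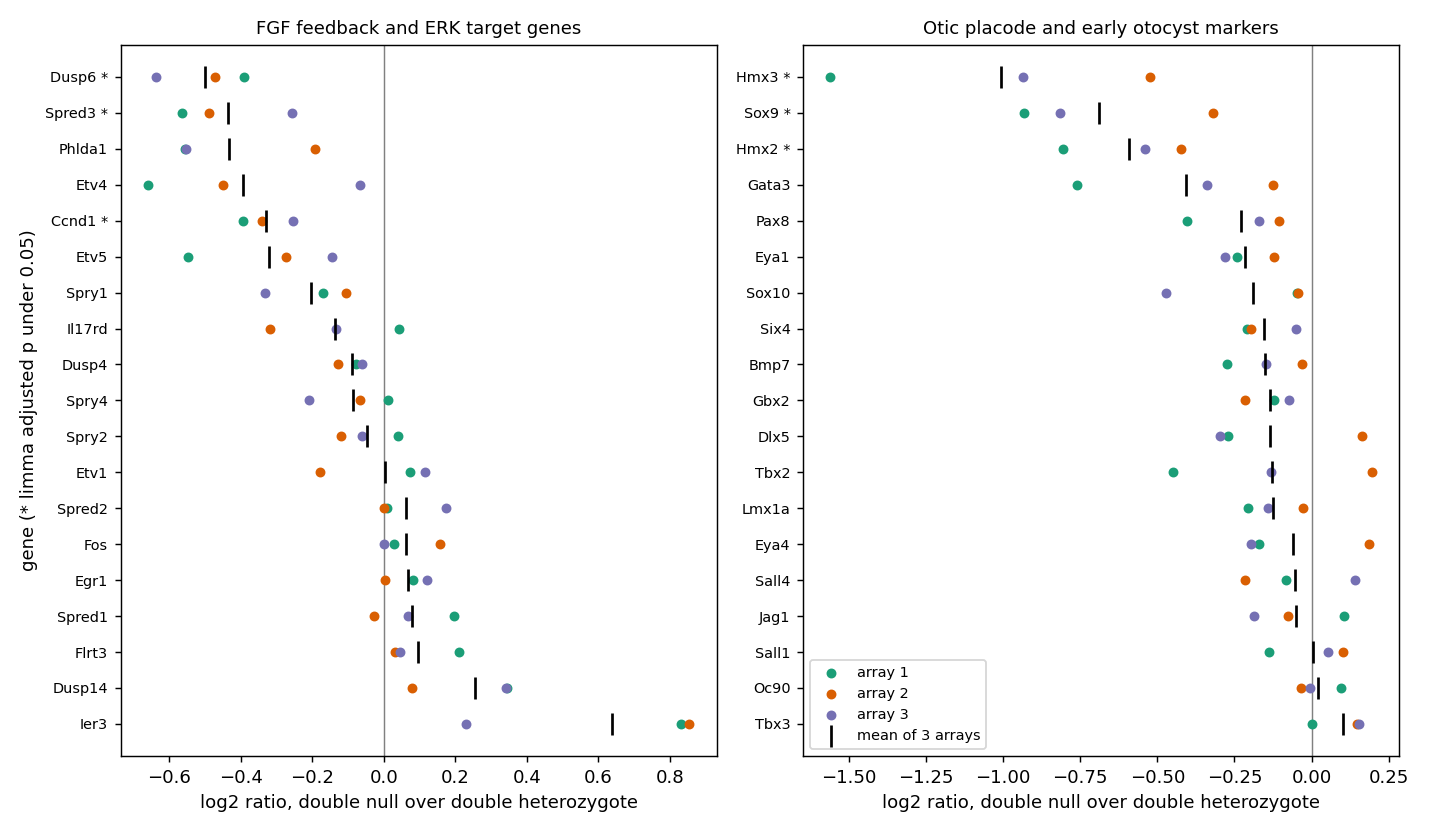
Log2 ratio of double null over double heterozygote (horizontal axis) for most tested members of the FGF feedback and otic lists (vertical axis), with a coloured point for each of the 3 arrays and a black bar for their mean. Hmx3, with array values of -1.56, -0.52 and -0.94, and Dusp6, with -0.39, -0.47 and -0.64, lie below 0 on every array.

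The preplacodal list, genes of the wider ectodermal field from which placodes arise, had 1 of 12 members lower over all genes, and over the list alone 3 lower and 2 higher, among the latter Gata2 at 0.20 with a second probe at 0.05 (camera adjusted p = 0.113). Surface ectoderm and epithelial genes were lower as a list, with a median of -0.12 over 16 members (camera adjusted p = 0.00781, and adjusted p = 0.637 with an estimated correlation). None passed over all genes, and over the list alone Cdh1 (-0.30) and Cldn7 (-0.38), both of cell junctions, passed. The list's array medians were -0.22, 0.0025 and -0.10. Anterior placode genes (Pax6 -0.02, Pax3 0.07) and placodal neurogenesis genes had camera adjusted p = 0.853 each, and the sensory neuron gene Pou4f1 (-0.30, second probe -0.03) passed over its list alone.

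Markers of neighbouring tissues gave mixed results. Hindbrain and neural plate genes were lower as a list (median -0.14, camera adjusted p = 0.0321, and adjusted p = 0.432 with an estimated correlation), and the rhombomere genes Egr2 (-0.31) and Hoxb1 (-0.31) passed over the list alone. Blood and endothelial genes were higher as a list, with all 9 tested members above 0, a median of 0.43 and camera adjusted p = 0.00685, but adjusted p = 0.533 with an estimated correlation, and 0 members passed. Embryonic globin Hbb-bh1 had array values of 1.43, -0.51 and 2.69 (mean 1.20), and Ramp2 had a mean of 0.13. Neural crest genes (Crabp1 -0.10, Erbb3 -0.22) had camera adjusted p = 0.182 and head mesoderm genes (Prrx2 -0.02, Tbx1 -0.18) 0.896, with 0 members past the threshold in both. Among endoderm genes (camera adjusted p = 0.853), Sox17 fell by 0.54 (adjusted p = 0.0139, second probe -0.36), and Afp (0.25) passed over the list alone.

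Of the signalling lists, canonical Wnt targets were lower (median -0.12, camera adjusted p = 0.0389, and adjusted p = 0.432 with an estimated correlation). Lef1, a Wnt-responsive transcription factor gene, fell by 0.30 (adjusted p = 0.0342), though its second probe gave -0.00255, and the Wnt inhibitor gene Dkk1 (0.36, second probe 0.12) passed in the other direction over the list alone. In the retinoic acid list (camera adjusted p = 0.853) Cyp26a1, which degrades retinoic acid, fell by 0.35 (adjusted p = 0.0192). Over that list alone 4 members rose, among them Aldh1a2 (0.25). BMP targets (Id2 0.11, Id1 -0.02; camera adjusted p = 0.343) and Notch genes (Hes5 -0.11, Jag1 -0.05; camera adjusted p = 0.316) had 0 members past the threshold.

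Hypoxia and glycolysis genes had the smallest camera p of the raised lists, with a median of 0.22 and adjusted p = 1.14e-05, and adjusted p = 0.432 with an estimated correlation. Adm, Ldha, Pgk1 (0.73, second probe 0.80), Aldoa (0.50, second probe 0.37) and the glucose transporter gene Slc2a1 (0.44) passed over all genes, of which all but Adm lay in the bright range, and with the processed signals Aldoa turned to -0.03. Reference genes were also higher (median 0.13, camera adjusted p = 0.0416, and adjusted p = 0.432 with an estimated correlation), and Eef1a1 (0.59, second probe 0.53) and Rplp0 (0.61) passed over all genes. The other Rplp0 probes gave -0.05 and 0.82. Adjusted over the list alone 5 members rose and 1 fell, with Tbp (0.19, second probe 0.018) and B2m (0.19, other probes 0.18 and 0.22) among the rises. In the cell cycle list (camera adjusted p = 0.343) the bright replication genes Mcm3 (0.49) and Pcna (0.32) rose. A second Mcm3 probe gave -0.01, and with the processed signals Mcm3 was at 0.21 and Pcna at 0.013, with both calls lost. In the dissociation and stress list (camera adjusted p = 0.343) Junb rose by 0.39 (adjusted p = 0.0159), while its second probe gave 0.05.

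p53 targets were lower as a list (median -0.07, camera adjusted p = 0.0389, and adjusted p = 0.432 with an estimated correlation) with 0 members past the threshold, Aen at -0.08 and Zmat3 at -0.14. Basement membrane and matrix genes had camera adjusted p = 0.113, and Lama5 (-0.24) and Has2 (-0.33, second probe -0.72) passed over the list alone. Genes flanking Fgf3 and Fgf10 were lower (median -0.06, camera adjusted p = 0.0389, and adjusted p = 0.432 with an estimated correlation). Ccnd1, also in the FGF list, fell over all genes, and Cttn (-0.22, second probe 1.2e-05), Zfp131 (-0.28), Paip1 (-0.18) and Fgf15 passed over the list alone, although the other Paip1 probes gave 0.37 and 0.17. Sex-linked genes had camera adjusted p = 0.853 and differed between arrays: the Y-linked gene Eif2s3y was at -0.65, 1.97 and -0.31, and Xist at 0.86, -1.26 and 0.22, with means of 0.27, 0.12 and 0.36 for its other probes. Among the called lists, the estimated correlation was below the preset 0.01 for the FGF feedback (-0.00085), hindbrain (-0.04), Wnt (-0.06), p53 (-0.02) and flanking (-0.07) lists. Their larger p with it therefore does not come from correlation between genes. For the otic (0.22), epithelial (0.46), blood (0.44), hypoxia (0.04) and reference (0.04) lists it was above. That form of camera rests on the residual degrees of freedom of 3 arrays, so a lost call decides little. With fry 0 lists passed in one direction (lowest adjusted p = 0.0745) and 11 passed for change in either direction. The otic list passed in neither form, and neither did the epithelial, hindbrain, blood and p53 lists. Here fry takes correlation between the genes of a list into account. Its direction was up for the FGF ligand and head mesoderm lists and down for the retinoic acid list, opposite to camera in each.

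**Figure D3:**
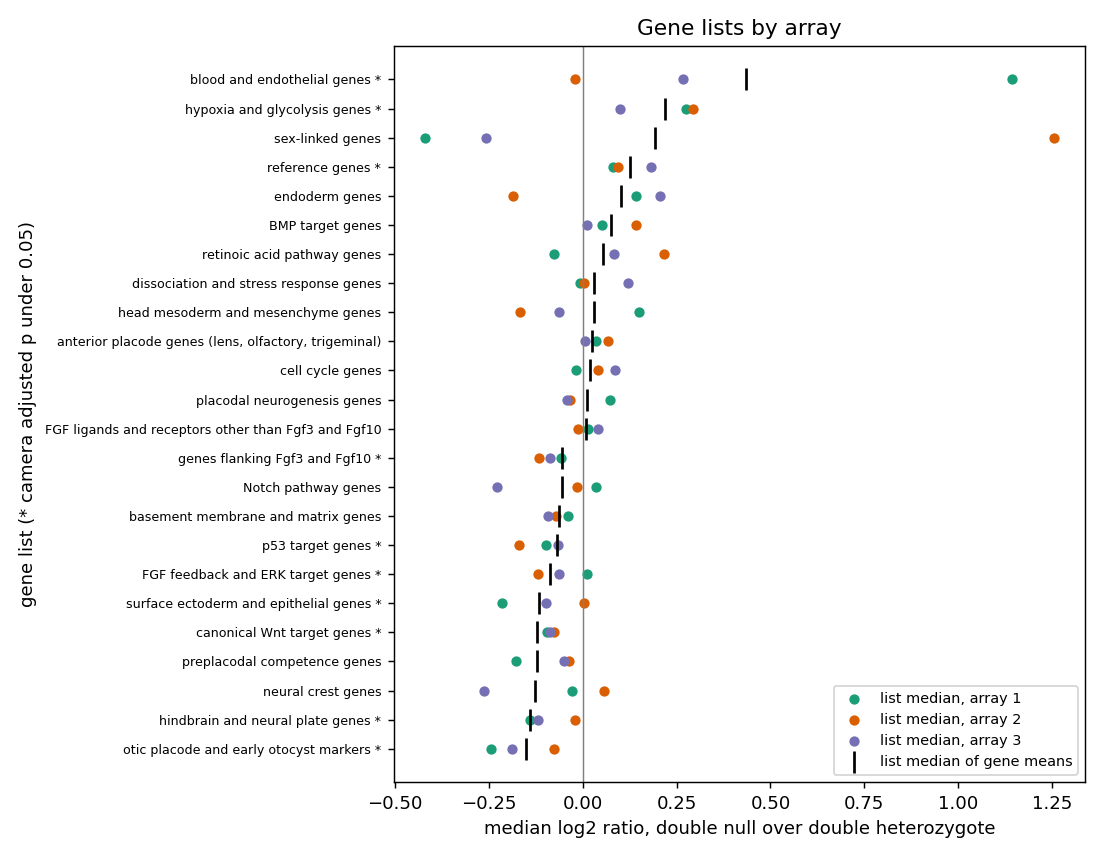
Median log2 ratio of double null over double heterozygote (horizontal axis) of each of the 24 gene lists (vertical axis), with a coloured point for each of the 3 arrays and a black bar for the median of gene means. The otic list has array medians of -0.24, -0.08 and -0.19, and the blood and endothelial list has 1.14, -0.02 and 0.27.

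Labelling controls spiked into both RNAs, 10 probes with 32 spots each, gave mean log2 ratios between -2.21 and 2.84. Each of the 10 probes was higher on array 3 than on array 1. The intended ratios were not given in the sources used here.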

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

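The loess spans of 0.3, 0.1 and 0.05 on probes above background, the limit to intensity 15 and the recentring of median-centred ratios were chosen after seeing the data; the other alternatives were planned. The 7 called FGF feedback and otic genes were below 0 in all 21 alternatives fitted gene by gene, though with median centring Dusp6 was at -0.16 (adjusted p = 0.0733) and Ccnd1 at -0.083 (adjusted p = 0.228), and with the mean of all probes Sox9 was at -0.37 (adjusted p = 0.108). All 7 lost the threshold in 6 of these: processed signals, series table, spans 0.1 and 0.05, intensity up to 15 and without replicate 3. Several of the 21 could not turn a sign, so the shared direction there is no support. The intensity trend, separate channels and the limit to intensity 15, for example, left the ratio of Hmx3 at -1.006. Leaving out 1 array cannot turn a gene with one sign on all 3. The 411 calls (93 lower, 318 higher, 77.4% higher) became 227 with an offset of 16, 180 (14 lower, 166 higher) with separate channels and no replicate block, 983 (61.7% higher) with an intensity trend, 1116 (63.8% higher) at adjusted p under 0.10 and 14 at 2-fold or more. They became 242 with span 0.3, 24 (5 lower, 19 higher) with span 0.1, 17 (1 lower, 16 higher) with span 0.05, 21 up to intensity 15 and 68 to 276 with 1 array left out (68 without replicate 3, 94.1% higher; 220 without replicate 2). limma called 0 with processed signals (3218 at unadjusted p under 0.05), 0 with the series table (3268 at unadjusted p under 0.05) and 0 with treat (61 at unadjusted p under 0.05). The main fit had 3733 genes at unadjusted p under 0.05.

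Median centring on all spots gave 13349 calls (1452 lower, 11897 higher), with medians of the tested genes at 0.40, 0.35 and 0.34 on the 3 arrays. Recentred on the tested genes, which is the form used for all other values here, it gave 8893 (4912 lower, 3981 higher). Of the 10 called lists, 5 kept the call with offset 16, 3 with processed signals, 3 with the series table, 4 with span 0.3, 4 with span 0.1, 3 with span 0.05 and 0 with an estimated correlation. With median centring 3 lists were called, all of them higher in the double null, and 2 of them were among the 10. Without replicates 1, 2 and 3 in turn, 8, 9 and 7 were called, of which 8, 6 and 7 were among the 10. The otic list kept its call with processed signals (camera adjusted p = 0.000658) but lost it with median centring, as did the other lowered lists. Fgf3 ranged from -0.69 to -0.37 with 1 array left out, passed without replicate 2 (adjusted p = 0.0177) and passed with median centring (-0.53). Fgf10 ranged from 0.06 to 0.27 with 1 array left out and was 0.0050 with median centring.

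Signs turned in these cases. With median centring they were Pax6 (0.18), Egr2 (0.045), Crabp1 (0.28), Prrx2 (0.26), Tbx1 (0.018), Afp (-0.062), Id1 (0.34), Hes5 (0.16), Jag1 (0.19), Aen (0.21), Zmat3 (0.041), Xist (0.24) and the test of the flanking list (median -0.064). With processed signals and with the series table they were Pax6 (0.0023), Prrx2 (0.014) and Aldoa (-0.030). With span 0.1 they were Pax6 (0.0065), Prrx2 (0.016), Pcna (-0.0050), Aldoa (-0.041) and Slc2a1 (-0.0017), and with span 0.05 Pax6 (0.0056), Prrx2 (0.023), Pcna (-0.030), Aldoa (-0.15), Slc2a1 (-0.072) and Rplp0 (-0.091). With the mean of all probes they were Pax6 (0.055), Jag1 (0.080), Xist (0.17) and Paip1 (0.12). With 1 array left out, Pax6 ranged from -0.16 to 0.086, Pax3 from -0.00070 to 0.11, Crabp1 from -0.30 to 0.0011, Prrx2 from -0.043 to 0.0073, Ramp2 from -0.021 to 0.21, Jag1 from -0.13 to 0.016, Xist from -0.52 to 0.54 and Eif2s3y from -0.48 to 0.83.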

Other observations

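All tests in this part were chosen after the results were seen.

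Genes of heart and muscle were not among the fixed lists. In a list of 32 heart and cardiac progenitor genes written after the largest rises had been seen, 23 were tested and 6 passed the threshold, all higher in the double null. They were Tnni1, Popdc2 (0.81), Unc45b (0.72), Gata6 (0.74), Myl4 (0.54) and Hand1 (0.31), with limma adjusted p between 0.0043 and 0.0481. Of these, 4 were among the genes whose rise had prompted the list. Tnnt2 (0.76) and Myl7 (0.59) did not pass, and Myl7 had array values of 0.03, 0.64 and 1.09.

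A candidate explanation for the higher ratios of the called heart genes is the presence of cells from the heart region in the double null pools. The muscle determination gene Myod1 was not in the list, so its rise was not examined here. Leaving out the 6 genes first noticed (Tnni1, Popdc2, Unc45b, Gata6, Myocd and Myh6), 2 of 17 tested members passed, Myl4 and Hand1, and 14 were above 0, with a median of 0.10 rounded from 0.09529. camera gave p = 0.000358 at its preset correlation and p = 0.0615 with an estimated one. The heart genes did not rise alike, with Acta2 at 0.02 and Myh7 at 0.31. Blood and endothelial genes, which tissue carried over with the heart region could also bring, were above 0 in 9 of 9 cases. Their array medians were 1.14, -0.02 and 0.27, against 0.09, 0.19 and 0.15 for the 17 heart genes. The explanation stays open, as does an effect of genotype on the same genes.

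The rise of the brightest genes may come from a brightness-dependent dye trend that the loess left in place. Of 249 tested genes with mean log2 intensity over 16, 97.2% lay above 0. The rise was not confined to ribosomal protein genes, since 96.3% of the 191 others were above 0 (median 0.41). This share restates the rise, and a rise of abundant transcripts would give it too, so it does not separate the explanations. Dimmer probes, available for 46 of the called bright genes, had a median of 0.0050 against 0.50 for the bright probes, but dimmer probes of 44 called genes of lower intensity lost as much (0.02 against 0.35), so this comparison does not separate the explanations. The comparison of probes had been meant to help decide, and was set aside only after these values were seen. Taken as first meant, it would have gone with the dye trend. A rise of abundant transcripts in the double null stays open, since no array has the dyes swapped.

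For the fall of the 7 called FGF feedback and otic genes, a smaller share of ectoderm in the double null pools would lower epithelial genes by about as much. The median of the epithelial list lay above that of the 7 genes on all 3 arrays, by 0.44 ± 0.06 on average (SE over arrays), but the 7 genes were chosen for falling, so this gap decides nothing. Over the whole otic list the gap was 0.07 ± 0.02, and 14 of 16 epithelial genes were below 0, so a smaller share of ectoderm stays open. The Y-linked genes had a median of 1.39 on array 2 and -0.44 and -0.26 on the others. The 7 genes were below 0 on every array, but all 411 called genes had one sign, so selection alone gives this. The whole otic list, fixed beforehand, also had array medians below 0 (-0.24, -0.08 and -0.19). This argues against a different share of male embryos as the only cause. The 7 genes fell least on array 2 (median -0.42, against -0.56 and -0.64), as did the otic list, so a part played by sex stays open. Probe-specific dye effects cannot be told apart from genotype, because the dyes were never swapped. Of the 7 genes, 2 had other kept probes, and in both these were below 0. For Sox9, however, 1 of them was at only -0.0040. The calls of the 7 genes ended with span 0.1 although, for example, Hmx3 stayed at -1.03 ± 0.18 against -1.01 ± 0.18. They also ended with processed signals, where ratios and standard errors of some genes grew. Hmx3 was at -1.28 ± 0.27 there and Hmx2 at -0.87 ± 0.16 against -0.59 ± 0.08, while Sox9 stayed at -0.68 ± 0.14. An effect of the genotype itself stays open and was not tested apart from these.

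Turning the sign of the ratios of single arrays gives 4 distinct patterns, of which 1, the real one, gave as many calls (411, against at most 0 in the others). With 4 patterns the share cannot go under 0.05.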
